A study of Homo sapiens with 6 samples.

How the data were processed

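RNA was measured by stranded poly-A sequencing (TruSeq Stranded mRNA kit, Illumina NextSeq) in 6 libraries, 3 each of the MCF-7 lines MCF7EV and MCF7-FGFR1(SP-)(NLS), at a passage under 10 and with an RNA integrity number of at least 8, per the labels' protocols. The authors deposited a table of 26485 genes with a column of estimated counts for each library. Per the submitters' processing notes TopHat, Subread and featureCounts were used with the genome build hg38; versions, settings, the strand setting of the counting and the annotation are not given in the sources used here. The layout of the table is that of featureCounts per the file headers, and its gene coordinates are printed as it gives them. Most values were whole (within 1e-09), but 11.2% to 13.3% of the values in each library were not, as counting a read in parts for several genes or positions gives. Genes with such values are called genes with split reads and their levels are uncertain; they made up 25.4% of the genes tested, and among the genes named also include CDT1, G6PD, AKR1B10, NQO1, SOX2, FDFT1, RPL9, TAPBP, LYZ, HLA-F and HLA-DRB1. Because no strand setting is known, reads of overlapping or antisense genes cannot be told apart, which concerns PGR, TGFB2, PCNA, CCNA2, LOXL2, COL5A1, ITGB2, HSPE1, HLA-F, HLA-DRB1, BHLHE40, IGF1R, ACAT2, LGR4 and SLC7A11 among the genes named.

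Each column was matched to its sample by the line and replicate number in its name. The deposited counts were rounded to whole numbers, since the design fixed before the data were examined assumed whole counts. Totals per library ran from 21479753 to 39842077 counts, the 10 most abundant genes took 4.5% to 5.3% of each library, and TMM factors lay between 0.994 and 1.011. Replicates were compared by a chi-square of their counts per gene, which was 2.33 to 16.9 within a line, above the value near 1 that sampling alone gives, so that no library was treated as a copy of another. On log2 CPM the first principal component held 52.0% of the variance and separated the lines; the second held 17.7% and set MCF7EV replicate 2 and MCF7-FGFR1(SP-)(NLS) replicate 3 apart from the rest.

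Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with its default settings left 15720 genes, TMM factors scaled the libraries, and a robust quasi-likelihood F test compared the lines with no other term. P-values were adjusted by the Benjamini-Hochberg method over all genes tested and 0.05 was the threshold, with no limit on the fold. The biological coefficient of variation was 5.86%. The SE of a log2 fold change was taken as its unshrunken estimate divided by the root of F and is approximate. In 6385 genes (40.6%, where chance gives 10%) the libraries of one line all lay above those of the other. On data simulated for this comparison with 15720 genes, the test recovered 48% of genes changed by 1.25-fold, 78% at 1.5-fold, 94% at 2-fold and 100% at 4-fold (50 genes each), and 16 of 176 calls (9.1%) were false. Far fewer genes were changed there than were called in the data, so these shares need not hold for the reported calls.

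Fixed before the data were examined were 29 gene lists, the design and the alternatives, except where said. Of 701 list symbols 687 were found in the table, 22 of them by an older symbol through a RefSeq gene table. The mitochondrially encoded genes had no row in the table and were not analysed here, which left 28 lists. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists, and again with a correlation estimated per list and with fry. Of the 9 lists called, the list of G1/S and replication genes alone held with an estimated correlation. In simulated data 1 of 100 random lists had p under 0.05. Lists drawn at random are not made of genes that move together, so this does not test calls for lists that are. In the real libraries each of the 9 other splits into 3 and 3, given at the end, called 3 to 8 lists. These splits keep part of the difference between the lines, so they do not give the number called without a difference. The count of members that pass is given over all genes tested and adjusted over the list alone.

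The genes named are FGFR1, ESR1, PGR, GREB1, TFF1, MYC, CCND1 and the other FGF receptors; the 10 largest rises and 10 largest falls among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between the libraries of the lines; and the 3 members of each list with the smallest adjusted p. Others are said to be named after their values were seen.

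Alternatives were size factors of DESeq2 1.42.0, library size alone, no filter on low counts, a filter of at least 50 counts in 3 libraries, the DESeq2 Wald test, limma-voom, glmTreat against 1.5-fold, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were a fit on genes with whole values, libraries thinned to the smallest total, removal of smooth trends on GC content and gene length (GC content from GENCODE transcripts, known for 96.3% of tested genes), and list counts under these and with each library left out. Chromosome medians, windows of 60 genes and gene families grouped by symbol stem were also examined after the main results.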

Results

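Polyadenylated RNA was sequenced from 2 lines derived from MCF-7, an established estrogen receptor-positive human breast cancer cell line. The control line, MCF7EV, carried an empty vector. The other line, MCF7-FGFR1(SP-)(NLS), carried a form of the fibroblast growth factor receptor FGFR1 that lacks the signal peptide and bears a nuclear localisation signal. Each line was represented by 3 libraries, described by the submitters as biological replicates, from cells kept for 48 h in medium deprived of estradiol. Total counts over genes were 27681193, 21479753 and 35155595 for MCF7EV replicates 1, 2 and 3, and 27906188, 34417034 and 39842077 for MCF7-FGFR1(SP-)(NLS) replicates 1, 2 and 3. The comparison asked which transcripts differ between these 2 lines. No line carried another form of FGFR1, and the location of the protein was not measured here. The comparison therefore cannot tell nuclear location from added FGFR1 or from other differences between the lines. Levels are normalised CPM (counts scaled by TMM-adjusted library size), given as mean ± SD with n = 3 per line, and log2 fold changes are MCF7-FGFR1(SP-)(NLS) over MCF7EV with an approximate SE.

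FGFR1 transcripts were higher in the line that carries the construct. The gene lies on chromosome 8 at 38411138 to 38468834 (hg38, minus strand), and reads over its exons came to 27.2 ± 2.21 CPM in MCF7EV and 52.98 ± 0.768 CPM in MCF7-FGFR1(SP-)(NLS), a 1.94-fold rise (log2 fold change 0.96 ± 0.06, adjusted p = 3.6e-06, edgeR quasi-likelihood test). The levels in the 3 MCF7EV libraries were 29.2, 24.8 and 27.6 CPM, and those in the 3 MCF7-FGFR1(SP-)(NLS) libraries were 53.8, 52.8 and 52.3 CPM. Counts per gene do not separate reads of the construct from reads of the cell's own FGFR1. The 10 nearest tested genes, between 38176588 and 39105260 on the same chromosome, had a median log2 fold change of -0.08 and ranged from -0.46 to 0.18. Among the other FGF receptor genes, FGFR2, which held split reads (counted in parts over several genes or positions, so that its level is uncertain), fell from 25.6 ± 1.31 to 14.5 ± 0.714 CPM (log2 fold change -0.83 ± 0.07, edgeR adjusted p = 2.3e-05) and FGFR4 rose from 11.6 ± 0.300 to 21.5 ± 3.09 CPM (0.90 ± 0.10, edgeR adjusted p = 1.3e-04). FGFR3 was at 22.6 ± 1.38 and 19.5 ± 2.85 CPM and did not pass the test (edgeR adjusted p = 0.16), although it did without MCF7-FGFR1(SP-)(NLS) replicate 3 (adjusted p = 0.0055). In the fixed list of FGF receptors and binding partners, which leaves out FGFR1, 2 of 17 tested members rose and 2 fell, and the same counts passed when adjusted over the list alone. The fourth of these calls by size of p, after FGFR2, FGFR4 and FGF13 (-0.37), was FGF18 (0.63), named after its values were seen. As a group the list did not differ from other genes (camera adjusted p = 0.93).

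**Figure D1:**
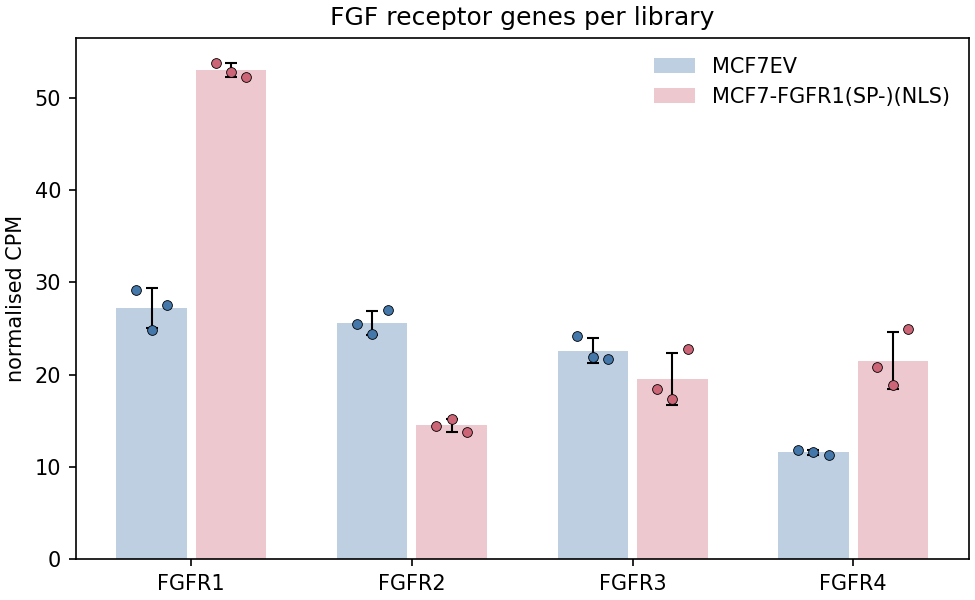
Normalised CPM of the 4 FGF receptor genes in each library. Bars are means, error bars the SD and points the 3 libraries of MCF7EV (blue) and of MCF7-FGFR1(SP-)(NLS) (red); FGFR1 lay between 24.8 and 29.2 CPM in MCF7EV and between 52.3 and 53.8 CPM in MCF7-FGFR1(SP-)(NLS), and FGFR2 was lower in the latter line.

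Beyond the receptor genes, differences between the lines were many and mostly small. Of 15720 genes tested, 1729 were higher and 1878 lower in MCF7-FGFR1(SP-)(NLS) at an adjusted p under 0.05 (edgeR), and the median change among these 3607 genes was 1.26-fold. Changes of over 2-fold were found for 185 of the higher and 61 of the lower genes. Among the largest rises, CADPS, a factor for the release of dense-core vesicles, was close to absent in MCF7EV, with 1, 0 and 5 reads in the 3 libraries, and reached 384, 514 and 556 reads in MCF7-FGFR1(SP-)(NLS). Summed over each line, without TMM scaling, this was 0.0712 CPM (95% exact Poisson interval 0.0261 to 0.155, counting error only) against 14.2 CPM (13.5 to 14.98). MGP, the matrix Gla protein that limits calcification, rose from 4.18 ± 0.890 to 22.4 ± 2.59 CPM, and COL4A6, a basement membrane collagen chain, from 4.81 ± 0.843 to 17.8 ± 1.95 CPM. The other genes among the 10 largest rises were DMP1 (log2 fold change 2.11), S100A7A (2.02), DUSP13 (1.85), CHGA (1.69), the keratin gene KRT17 (1.67), ANXA8L1 (1.67) and S100A7 (1.66). S100A7A, S100A7 and ANXA8L1 held split reads, so their values are uncertain.

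The largest fall was that of PRKG2, a cGMP-dependent protein kinase, from 19.6 ± 0.105 to 0.811 ± 0.296 CPM (log2 fold change -4.63 ± 0.16, edgeR adjusted p = 2.4e-08). SHH, the secreted ligand of the hedgehog pathway, fell from 62.6 ± 2.25 to 11.7 ± 1.26 CPM, and INHBB, which encodes a subunit of activin B and inhibin B, from 71.1 ± 0.905 to 20.97 ± 0.767 CPM. MITF, a transcription factor best known from pigment cells, fell from 24.3 ± 2.10 to 8.60 ± 0.164 CPM, and CA2, a carbonic anhydrase, from 30.3 ± 2.63 to 10.6 ± 0.889 CPM. The guidance molecule SEMA3D (-2.29), the cathepsin gene CTSV (-1.79), SNTB1 (-1.68), C3orf70 (-1.60) and ARHGAP26 (-1.41) made up the rest of the 10 largest falls, of which C3orf70 and ARHGAP26 held split reads. For each of these 20 genes the 3 libraries of one line lay wholly above the 3 of the other, which was a condition for naming them. The 10 nearest tested neighbours of CADPS (median log2 fold change 0.07) and of PRKG2 (-0.03) did not move with them as a group.

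**Figure D2:**
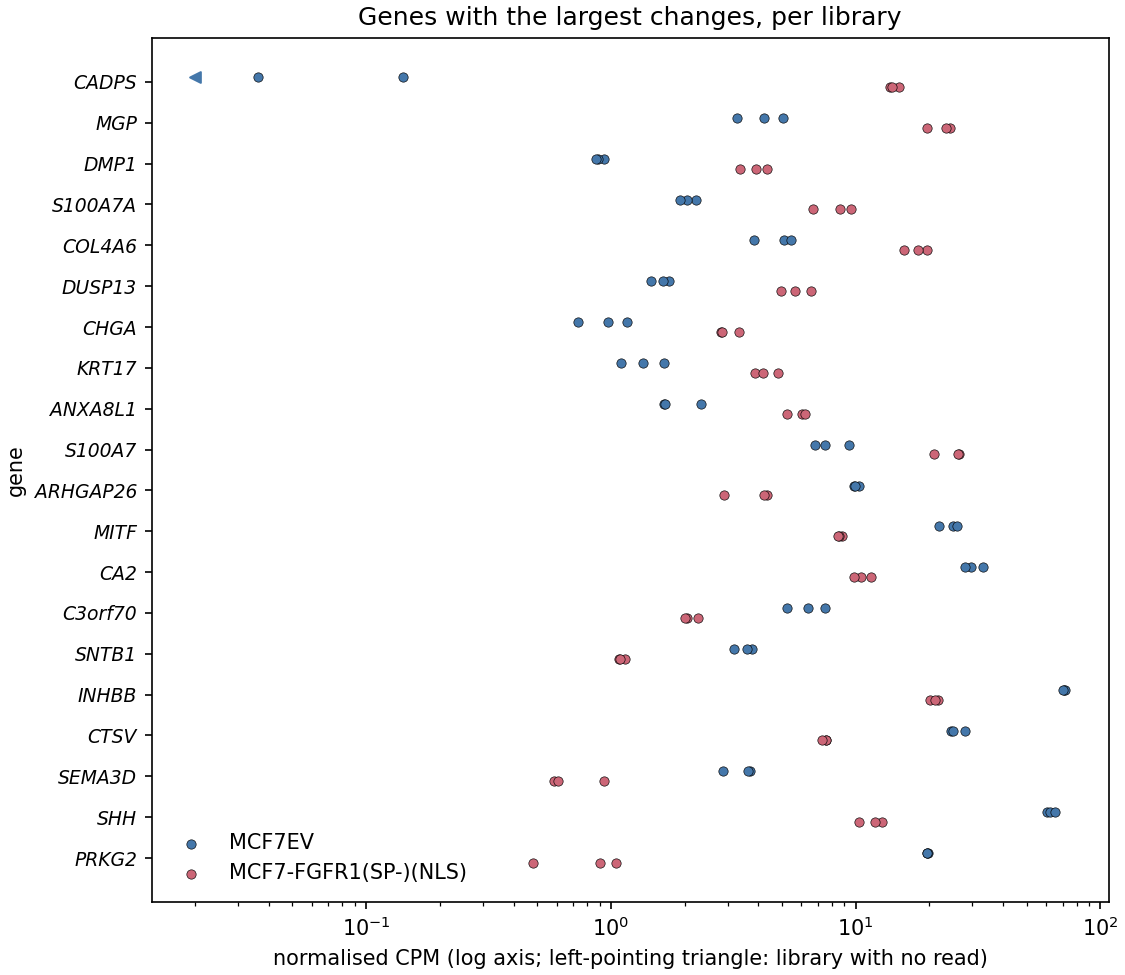
Normalised CPM (log axis) of the 10 genes with the largest rise and the 10 with the largest fall that met the naming rule. Points are the 3 libraries of MCF7EV (blue) and of MCF7-FGFR1(SP-)(NLS) (red), and the triangle marks the MCF7EV library with no CADPS read; SHH fell from a mean of 62.6 to 11.7 CPM.

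Genes of the cell division cycle were lower together in MCF7-FGFR1(SP-)(NLS). Of 35 tested genes of the G1/S transition and DNA replication, 34 fell and none rose, with a median log2 fold change of -0.39, and 34 fell when adjusted over the list alone. PCNA, the sliding clamp of the replicative polymerases, fell from 166 ± 8.44 to 114 ± 1.18 CPM, CDC45, a part of the replicative helicase, from 43.0 ± 2.64 to 26.6 ± 1.16 CPM, and SLBP, which binds histone messenger RNA, from 70.2 ± 1.06 to 48.3 ± 2.27 CPM. Of 35 genes of G2/M and mitosis, 34 fell and none rose, again 34 when adjusted over the list alone, with a median of -0.47. TOP2A, a DNA topoisomerase, fell from 264 ± 10.6 to 170.4 ± 7.22 CPM, cyclin A2 (CCNA2) from 69.1 ± 0.970 to 46.1 ± 1.61 CPM and the spindle assembly factor TPX2 from 176 ± 1.21 to 125 ± 3.73 CPM. The members that did not pass were CDT1 (-0.15, edgeR adjusted p = 0.37) and BUB1B (-0.13, adjusted p = 0.16), named after their values were seen. Against other genes, camera gave adjusted p = 5.3e-20 for the G1/S list and 2.6e-21 for the G2/M list. With an estimated correlation the G1/S list kept its call (adjusted p = 0.011) and the G2/M list did not (adjusted p = 0.17). MYC (115 ± 11.2 and 113 ± 4.40 CPM) did not pass the test (edgeR adjusted p = 0.87), while cyclin D1 (CCND1) rose from 775 ± 11.6 to 888 ± 6.03 CPM (adjusted p = 0.0040).

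Interferon-induced genes moved the other way. In the type I interferon response list, 28 of 35 tested genes rose and none fell, or 30 when adjusted over the list alone, and the median log2 fold change was 0.55 (camera adjusted p = 7.2e-12; adjusted p = 0.40 with an estimated correlation). OAS1, an antiviral synthetase, rose from 11.6 ± 0.770 to 22.6 ± 2.37 CPM, STAT1, a transcription factor of interferon signalling, from 277 ± 9.82 to 360 ± 24.5 CPM, and DDX60, which held split reads, from 9.17 ± 2.03 to 19.5 ± 2.06 CPM. The mean centred log2 level of the list was -0.30, -0.46 and -0.24 in the MCF7EV libraries and 0.10, 0.39 and 0.51 in the MCF7-FGFR1(SP-)(NLS) libraries. Of 18 antigen presentation genes, 10 rose and 2 fell (12 and 2 when adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.0091; adjusted p = 0.46 with an estimated correlation). Of these genes 15 lie on chromosomes 6 and 15, whose genes were higher together, and subtracting chromosome medians left 43.7% of the median. The peptide-loading factor TAPBP (0.32) and the class I gene HLA-F (0.79) rose. Both falling members encode class II molecules, HLA-DRB1 (-0.53) and, named after its values were seen, HLA-DRA (-0.50). Reads of this family can be split between copies, and only 5 members rose without MCF7EV replicate 1 and 4 with GC content and length trends removed, and 1 fell without MCF7EV replicate 3. Leukocyte markers, the cell type list nearest to these genes, had 2 of 7 tested members higher and none lower (3 and none when adjusted over the list alone), ITGB2 at 2.41 ± 0.161 and 3.73 ± 0.664 CPM and LAPTM5 at 1.05 ± 0.127 and 1.61 ± 0.110 CPM. LYZ was at 2.45 ± 0.121 and 3.11 ± 0.289 CPM and did not pass. The leukocyte list was not called (camera adjusted p = 0.11), except without MCF7EV replicate 2 (adjusted p = 0.04995), and no member rose without MCF7-FGFR1(SP-)(NLS) replicate 1, without MCF7EV replicate 1 or without MCF7EV replicate 3. None of 6 fibroblast markers passed (0 also when adjusted over the list alone; camera adjusted p = 0.72), with log2 fold changes of 0.10 for COL5A1, -0.20 for FBN1 and 0.39 for COL6A3.

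In the list fixed as replication-dependent histones, 8 of 13 tested genes rose and 1 fell, also when adjusted over the list alone, with a median log2 fold change of 0.32 (camera adjusted p = 9.9e-04; adjusted p = 0.38 with an estimated correlation). HIST1H2BK (0.43, split reads) and HIST1H4H (0.70) rose, and the falling member was H1F0 (-0.53), a linker histone whose messenger RNA is polyadenylated and not tied to replication. Most replication-dependent histone messages have no poly-A tail, and these libraries were made from poly-A RNA. Without MCF7EV replicate 3, 5 members rose.

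Estrogen-responsive genes changed in both directions with more rises than falls. ESR1, which encodes estrogen receptor alpha, fell from 374 ± 15.8 to 313 ± 12.7 CPM (log2 fold change -0.26 ± 0.05, edgeR adjusted p = 0.0027). In the list of estrogen-induced genes 21 of 39 rose and 8 fell (23 and 8 when adjusted over the list alone), with a median of 0.17 (camera adjusted p = 0.0050; adjusted p = 0.46 with an estimated correlation). The receptor's target genes GREB1 and TFF1 rose from 815 ± 12.3 to 1159 ± 61.8 CPM and from 2713 ± 284 to 3786 ± 314 CPM, and GREB1 held split reads. PDZK1, also with split reads, rose from 28.7 ± 3.29 to 76.7 ± 6.28 CPM and ADORA1, an adenosine receptor, from 6.87 ± 0.870 to 14.8 ± 0.369 CPM, while the secreted glycoprotein STC2 fell from 673 ± 16.0 to 472 ± 3.92 CPM. The progesterone receptor gene PGR did not pass (124 ± 5.70 and 116 ± 12.1 CPM, edgeR adjusted p = 0.39). Of 24 estrogen-repressed genes 5 rose and 7 fell (7 and 8 when adjusted over the list alone), among them SYT12 (0.68), ERBB4 (-0.75) and TGFB2 (-0.68), with no call for the list (camera adjusted p = 0.51) and with 3 rising members without MCF7EV replicate 1 or 3. In the luminal epithelial list 8 of 22 genes rose and 2 fell (8 and 3 when adjusted over the list alone), and the list was not called (camera adjusted p = 0.34). ESR1 and ELF3 (-0.33) were the falling members and OVOL1 (0.31) rose, but the number of rising members was 2 without MCF7EV replicate 1, 3 without MCF7EV replicate 3 and 4 without MCF7-FGFR1(SP-)(NLS) replicate 1. Basal and myoepithelial markers had 7 of 17 members higher and 1 lower, also when adjusted over the list alone, with a median of 0.24 (camera adjusted p = 0.0091; adjusted p = 0.38 with an estimated correlation). TP63, a basal transcription factor, rose from 7.60 ± 0.233 to 15.1 ± 1.27 CPM and KRT17 from 1.37 ± 0.278 to 4.29 ± 0.464 CPM, the caveolin gene CAV1 fell (-0.83), and 4 members rose without MCF7EV replicate 3.

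Feedback genes of the MAPK pathway, which receptor tyrosine kinases induce through ERK, had 7 of 22 tested members higher and none lower (9 and none when adjusted over the list alone). Their median log2 fold change was 0.15 (camera adjusted p = 0.0050; adjusted p = 0.38 with an estimated correlation). SPRY4, an inhibitor of the pathway, rose from 4.84 ± 0.769 to 8.31 ± 0.350 CPM, the transcription factor gene ETV5 from 7.90 ± 0.307 to 12.6 ± 0.726 CPM and PHLDA1, which held split reads, from 25.4 ± 0.788 to 33.1 ± 2.97 CPM. Targets of NRF2, the regulator of antioxidant genes, fell more often than they rose. Of 20 tested members 9 fell and 3 rose (11 and 3 when adjusted over the list alone), with a median of -0.13 (camera adjusted p = 0.0091; adjusted p = 0.38 with an estimated correlation). AKR1C2 (-0.71), AKR1C1 (-0.67) and the cystine transporter gene SLC7A11 (-1.01) fell, all 3 with split reads, and SLC7A11 overlaps an antisense gene. The rising members, named after their values were seen, were ABCC2 (0.42), G6PD (0.22) and AKR1B10 (0.45), and 1 of the 20 rose without MCF7EV replicate 1, 5 without MCF7-FGFR1(SP-)(NLS) replicate 3 and 5 with GC content and length trends removed.

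**Figure D3:**
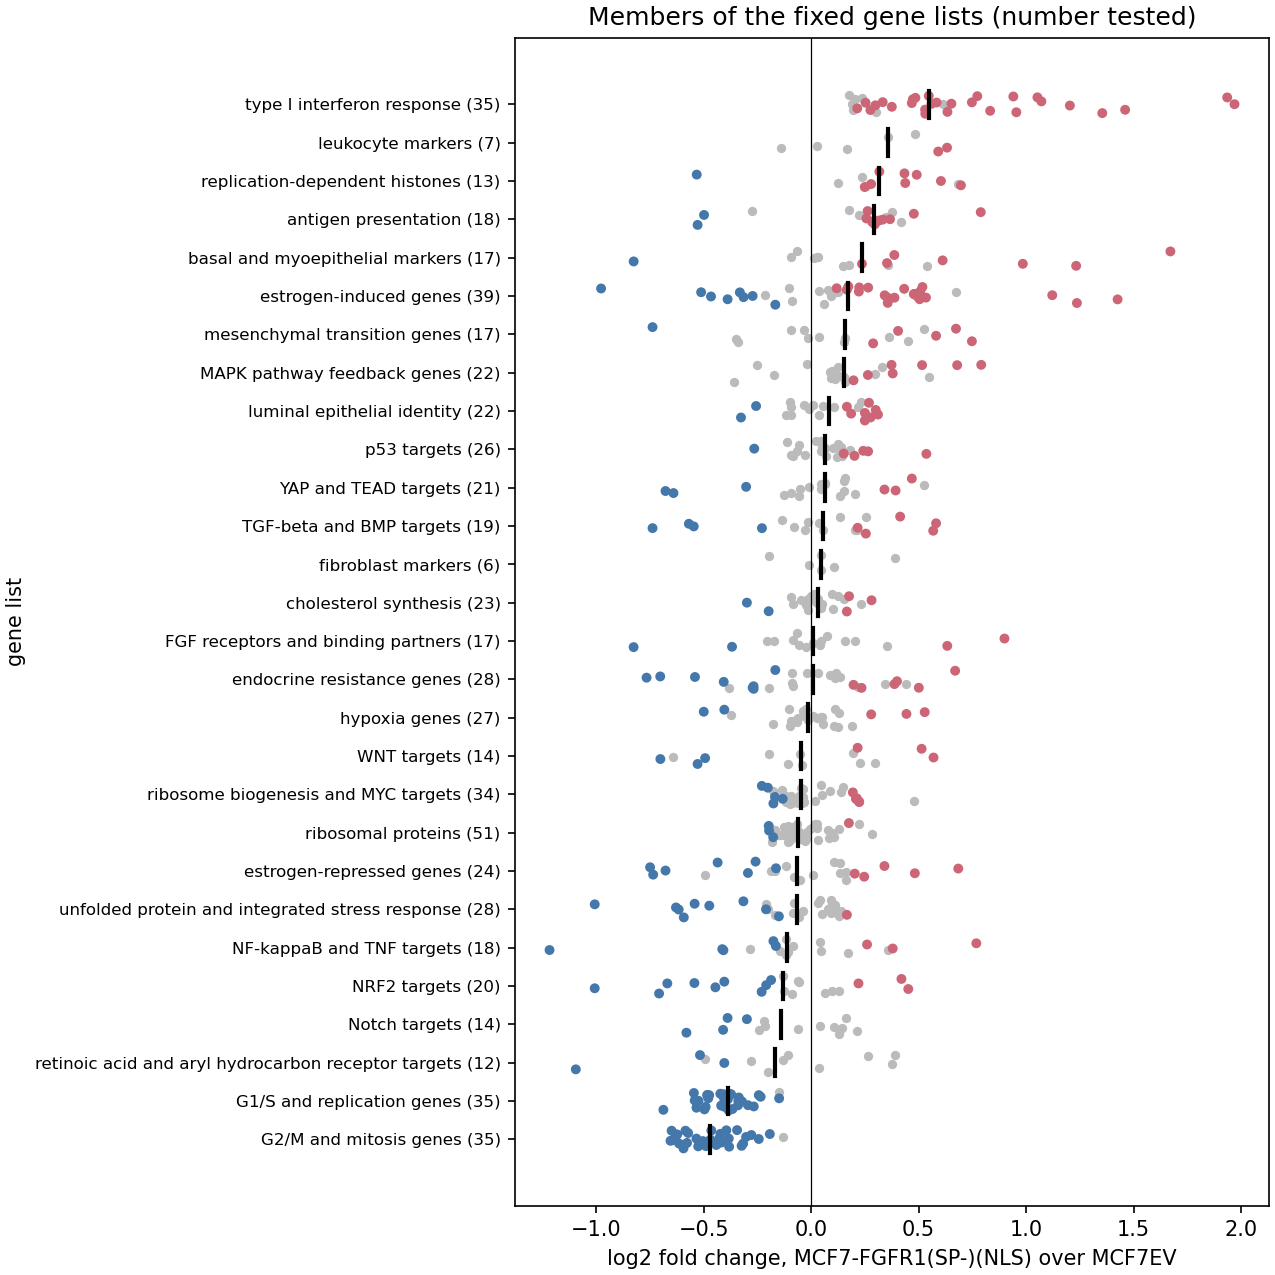
Log2 fold change (MCF7-FGFR1(SP-)(NLS) over MCF7EV, horizontal axis) of each tested member of the 28 gene lists with at least 5 tested members, 1 row per list with the number tested. Red and blue points are genes that rose and fell at an adjusted p under 0.05, grey points did not pass, and black bars are list medians, which run from -0.47 for G2/M genes to 0.55 for interferon response genes.

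The remaining lists were not called, though single members changed. For the unfolded protein and integrated stress response, 9 of 28 genes fell and 1 rose (11 and 1 when adjusted over the list alone; camera adjusted p = 0.084, but 0.035 without MCF7EV replicate 1 and 0.033 without MCF7EV replicate 3). The amino acid synthesis genes ASNS (-0.54) and PHGDH (-0.63) fell with SLC7A11, and XBP1 (0.17), named after its values were seen, rose. Of 12 targets of the retinoic acid and aryl hydrocarbon receptors 3 fell and none rose (3 and 1 when adjusted over the list alone; camera adjusted p = 0.11, but 0.038 without MCF7-FGFR1(SP-)(NLS) replicate 1), and the falls were CYP1B1, which went from 69.2 ± 6.27 to 32.5 ± 1.10 CPM, NQO1 (-0.40) and DHRS3 (-0.52). In the mesenchymal transition list 5 of 17 genes rose and 1 fell (6 and 1 when adjusted over the list alone; camera adjusted p = 0.14). Fibronectin (FN1) rose from 92.2 ± 5.80 to 155 ± 8.38 CPM, LOXL2 rose (0.67) and TGFBI fell (-0.74). Of 26 p53 targets 5 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.13). CDKN1A, which encodes the cell cycle inhibitor p21, rose from 417 ± 14.02 to 605 ± 26.6 CPM, and the calls for BTG2 (0.27) and DDB2 (-0.26) were lost without MCF7EV replicate 1 (edgeR adjusted p = 0.079 and 0.070).

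Among the endocrine resistance genes 6 of 28 rose and 8 fell (8 and 10 when adjusted over the list alone; camera adjusted p = 0.80), including RET (0.39), IGF1R (0.40) and SOX2 (-0.54), and the list's median was 0.0068, its mean -0.013 and its test direction downward. Notch targets had 4 of 14 lower and none higher, also when adjusted over the list alone (camera adjusted p = 0.33), with JAG1 (-0.30), NRARP (-0.41), HEY2 (-0.39) and, named after its values were seen, HEY1 (-0.58). NF-kappaB and TNF targets had 3 of 18 higher and 5 lower (3 and 6 when adjusted over the list alone; camera adjusted p = 0.47), with CXCL8 (-1.22), ICAM1 (-0.41) and ZC3H12A (0.26). The TGF-beta and BMP list had 5 of 19 higher and 4 lower (6 and 5 when adjusted over the list alone; camera adjusted p = 0.71), with BAMBI (-0.57), LTBP2 (0.57) and TGFBI. WNT targets had 3 of 14 higher and 3 lower (5 and 4 when adjusted over the list alone; camera adjusted p = 0.76), with DKK1 (-0.49), TNFRSF19 (-0.70) and LGR4 (0.51). YAP and TEAD targets had 3 of 21 higher and 3 lower (4 and 3 when adjusted over the list alone; camera adjusted p = 0.61), with ANKRD1 (-0.64), AJUBA (-0.30) and TGFB2. Hypoxia genes had 3 of 27 higher and 2 lower (1 and 2 when adjusted over the list alone; camera adjusted p = 0.97), with ENO2 (-0.50), MXI1 (-0.40) and BHLHE40 (0.53), and here too the median of -0.013 and the mean of 0.0017 differed in sign. Cholesterol synthesis genes had 3 of 23 higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.56), with LSS (0.28), ACAT2 (-0.30) and FDFT1 (0.17). The FDFT1 call was lost without MCF7EV replicate 1 or 3 and without MCF7-FGFR1(SP-)(NLS) replicate 1 or 2 (edgeR adjusted p = 0.12, 0.059, 0.054 and 0.057). Ribosomal protein genes had 1 of 51 higher and 3 lower (1 and 2 when adjusted over the list alone; camera adjusted p = 0.14), and RPL4 (0.18), RPL5 (-0.18) and RPL9 (-0.20) each lost their call without MCF7EV replicate 1 (edgeR adjusted p = 0.099, 0.063 and 0.096). RPL5 and RPL9 also lost it without MCF7-FGFR1(SP-)(NLS) replicate 1 (0.065 and 0.084) or 2 (0.052 and 0.060), and RPL9 without MCF7EV replicate 2 (0.057). The ribosomal protein list was called lower without MCF7-FGFR1(SP-)(NLS) replicate 3 (adjusted p = 0.0048) or without MCF7EV replicate 3 (adjusted p = 0.0064). Ribosome biogenesis and MYC targets had 5 of 34 higher and 5 lower (5 and 7 when adjusted over the list alone; camera adjusted p = 0.38), with NOP58 (-0.20), TCOF1 (-0.23) and HSPE1 (-0.18), whose call was lost without MCF7EV replicate 1 (edgeR adjusted p = 0.056) or MCF7-FGFR1(SP-)(NLS) replicate 1 (0.051).

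The number of members called varied with the libraries used. Calls over all genes did so too: 3607 with all libraries, 2137 without MCF7EV replicate 1 and 3886 without MCF7-FGFR1(SP-)(NLS) replicate 3. A call lost in such a fit is therefore not particular to the gene or list. With each library left out, at equal depth and with GC content and length trends removed, 93 of 448 list counts moved by more than 1.5 times. Falling ribosomal protein genes numbered 0 to 14 and rising ones 0 to 3. The falling ones were 14 without MCF7-FGFR1(SP-)(NLS) replicate 3, 7 without MCF7EV replicate 3 and 11 with the trends removed. Rising members numbered 1 to 10 for hypoxia genes and for p53 targets, and 1 to 8 for cholesterol synthesis genes. They numbered 0 to 7 for ribosome biogenesis and MYC targets, and 0 to 6 for the unfolded protein and integrated stress response, and all 5 of these lists had the most rising members with the trends removed. The range was 4 to 8 for mesenchymal transition genes, 3 to 6 for TGF-beta and BMP targets, and 2 to 5 for WNT targets. It was 1 to 4 for FGF receptors and binding partners, 1 to 3 for NF-kappaB and TNF targets and 0 to 1 for Notch targets. Falling members numbered 5 to 12 for the unfolded protein and integrated stress response, 4 to 11 for endocrine resistance genes, 3 to 9 for ribosome biogenesis and MYC targets, and 2 to 6 for NF-kappaB and TNF targets. They numbered 3 to 5 for retinoic acid and aryl hydrocarbon receptor targets, and 2 to 4 for hypoxia genes, for luminal epithelial genes and for FGF receptors and binding partners. Their number was 1 to 2 for cholesterol synthesis and for mesenchymal transition genes, 0 to 2 for p53 targets and 0 to 1 for leukocyte and for fibroblast markers.

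All p-values above compare these 2 lines, so any other difference between the cultures is part of each value. Camera calls at the preset correlation also arose when libraries of both lines were mixed, with 3 to 8 lists called in each of 9 such splits. Each mixed split holds unequal shares of the lines on its sides, so part of the line difference stays in it. These calls therefore do not show how many lists are called without a difference. Without MCF7EV replicate 1, 1008 genes were higher and 1129 lower, and with GC content and length trends removed FGFR3, PGR, FBN1 and LYZ passed as well (edgeR adjusted p = 0.0032, 0.0026, 0.015 and 0.023), while RPL5 lost its call (log2 fold change -0.09, adjusted p = 0.063).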

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

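The fits on whole values, equal depth and removed GC and length trends, and the list counts under left-out libraries, were chosen after seeing the data. FGFR1 stayed higher and past the threshold under every alternative run for single genes, with log2 fold changes of 0.90 to 1.01 with each library left out. The count of 1729 higher and 1878 lower genes was within 1.5 times under DESeq2 size factors (1783 and 1802), library size alone (1586 and 2141), no filter (1677 and 1919), the stricter filter (1688 and 1762), the DESeq2 Wald test (1437 and 1537), limma-voom (1664 and 1848), equal depth (1581 and 1658), whole values (1322 and 1477, with fewer genes tested) and removed trends (2478 and 2610). It moved further with glmTreat against 1.5-fold, to 81 higher and 29 lower. Of the called genes 2888 changed by less than that, and 492 higher and 227 lower genes by more. Most of the latter could thus not be shown to exceed 1.5-fold with 3 libraries per line. With each library left out the counts ran from 1008 to 1957 higher and from 1129 to 1929 lower, and the lowest of both came without MCF7EV replicate 1. Every gene called both in the reported fit and in one of these alternatives had the same direction in both. The replicate block gave 1024 higher and 1004 lower genes, of which 2010 were shared with the reported fit, all in the same direction. With this block BTG2, FDFT1, HEY2, HSPE1, LAPTM5, RPL4, RPL5 and RPL9 had adjusted p = 0.051, 0.093, 0.0502, 0.075, 0.080, 0.071, 0.074 and 0.079. The replicate numbers did not pair the samples: deviations of same-numbered samples correlated at -0.04, -0.11 and -0.19, and no sample correlated best with its own number. A pair of named genes changed sign, neither past the threshold before or after: COL5A1 (-0.015 with trends removed) and MYC (-0.059 to 0.062 with each library left out, above 0 without MCF7EV replicate 2), and the cause was not tested. The list test changed direction, never past the threshold, for FGF receptors and binding partners with fry (adjusted p = 0.50), without MCF7-FGFR1(SP-)(NLS) replicate 1 (0.81) and without MCF7EV replicate 2 (0.77), in a left-out range of 0.77 to 0.97. Hypoxia genes did so with fry (0.77), library size alone (0.95), the replicate block (0.89), and without MCF7-FGFR1(SP-)(NLS) replicate 1 (0.81), MCF7EV replicate 1 (0.85) or MCF7EV replicate 3 (0.98). Of the 9 called lists 8 lost their call with an estimated correlation, and 8 further lists passed with fry, which does not compare a list with other genes. LAPTM5 (log2 fold change 0.59) was not called at equal depth (0.61, adjusted p = 0.082), in the DESeq2 Wald test (0.60, adjusted p = 0.17) and with any library but MCF7-FGFR1(SP-)(NLS) replicate 3 left out, and the cause was not tested.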

Other observations

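The tests of co-regulated clusters, of copy number, of the antigen presentation genes' chromosomes and of the histones' region, and the bootstrap intervals, were chosen after the result they measure was seen, and work on chromosomes and gene families began after the main results. Gene families were formed from the letters at the start of the symbol, 280 of them with at least 8 tested members, and camera called 6 of them higher and 5 lower in MCF7-FGFR1(SP-)(NLS), none with an estimated correlation. The smallest p was that of the stem HIST, with 18 of 45 members higher, none lower and a median log2 fold change of 0.43 (camera adjusted p = 6.3e-06 over the families; adjusted p = 0.84 with an estimated correlation). This stem shares members with the fixed histone list and is not separate evidence. Its members HIST1H2BK (split reads) and HIST1H4H lie in a 60-gene window of chromosome 6 with a median of 0.33, histones included. The shift of that chromosome, described below, was not subtracted for the stem. Next came the keratins: 17 of 22 tested KRT genes rose in MCF7-FGFR1(SP-)(NLS) and none fell, with a median log2 fold change of 0.55 (camera adjusted p = 6.6e-06 over the families; adjusted p = 0.84 with an estimated correlation). KRT81 went from 78.9 ± 11.9 to 185 ± 22.9 CPM and KRT86 from 15.5 ± 1.47 to 30.9 ± 4.23 CPM, both hair keratins with split reads, and KRT7 from 10.6 ± 0.570 to 16.1 ± 1.59 CPM (SD, n = 3). The abundant luminal keratins KRT8 (0.30) and KRT18 (0.25), also with split reads, rose less. The stem COL, which includes a few genes that are not collagens, had 8 of 34 members higher and 1 lower (camera adjusted p = 0.045; adjusted p = 0.84 with an estimated correlation). Chromosome shifts were not subtracted for this or any other stem, so a change of a family cannot be told apart from shifts of its members' regions. COL4A5, the partner chain of COL4A6 in basement membranes, rose from 127 ± 1.67 to 260 ± 22.2 CPM, while COL3A1 was at 4.62 ± 0.132 and 4.61 ± 0.213 CPM. The lower stems with the smallest p were HAUS (6 of 8 members lower, camera adjusted p = 0.011), MCM (8 of 12 lower and 1 higher, 0.026) and RAD (10 of 20 lower, 0.043). The stems MCM and RAD share members with the fixed G1/S list and are not separate evidence. Apart from COL4A6, HIST1H2BK and HIST1H4H, the stems and genes in this paragraph were named after their values were seen.

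Near SHH, the gene LOC389602 had a log2 fold change of -2.10, the lowest of the 10 nearest tested genes. The median of these 10 was -0.17 and the highest 0.10, and 2 of them passed the threshold. The level and test result of LOC389602 are not given here, so a joint fall with SHH is not established.

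Genes of chromosomes 6 and 15 were higher together in MCF7-FGFR1(SP-)(NLS), with a median log2 fold change of 0.19 over 546 genes of chromosome 15 and 0.16 over 818 genes of chromosome 6, against 0.0063 over the genome, and 79.7% and 78.6% of their genes lay above 0 (permutation p = 1e-04 for each, the smallest that 10000 permutations can give; adjusted p = 2.1e-04). They were not alone: 19 of 23 chromosomes passed this test. Chromosomes 1, 6, 12, 15, 19, 21 and X passed as higher and the rest of these as lower, down to a median of -0.082 for chromosome 13. In 6 of them (1, 6, 12, 15, 21 and X) every MCF7-FGFR1(SP-)(NLS) library lay above every MCF7EV library. Among these were chromosomes 21 (median 0.12, 169 genes, 1 of 3 windows of 60 genes above the genome median by over 0.05) and 12 (0.071, 803 genes, 8 of 13 windows). In chromosome 8, which carries FGFR1, every MCF7-FGFR1(SP-)(NLS) library lay below every MCF7EV library (median -0.044). The permutation drew genes as independent, so its p-values do not allow for genes that move together. Removing GC content and length trends left the chromosome 15 median at 0.20, which argues against these trends as the cause. Equal depth left it at 0.19, but thinning keeps each gene's expected share of its library. It could hardly move the median, so a bias linked to depth is not excluded. A few co-regulated clusters are argued against by the 60-gene windows of both chromosomes, of which 95.7% (22 of 23) lay above the genome median by over 0.05, against 29 of 240 elsewhere. A copy number difference between the lines may account for the shift, but DNA was not measured. In the mean level of chromosome 15 the lowest MCF7-FGFR1(SP-)(NLS) library lay 0.14 above the highest MCF7EV library. Any steady difference between the lines gives such a gap, so it cannot tell copy number from other causes. Chromosome 20, which did not pass (permutation adjusted p = 0.7), had a gap of 0.013. An effect of the construct itself stays open and untested.

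The chromosome shift bears on lists that lie there, and shifts of regions bear on single genes too. RPL4 (0.18) lies on chromosome 15, whose median was 0.19. LSS (0.28) lies in a window of chromosome 21 with a median of 0.28. For these genes a change of their own cannot be told apart from the shift around them. Of the 18 antigen presentation genes 15 lie on chromosomes 6 and 15, and subtracting each gene's chromosome median left 43.7% of the list's median log2 fold change, so a change of these genes beyond their chromosomes cannot be told apart from the shift because the share left lies between the bounds set. Of the 13 histone genes 11 lie on chromosome 6, and subtracting chromosome medians left 85.2% of the list's median, above the bound of 50% written before this value was seen. The list's median member, HIST2H2BE (named after its values were seen), lies off chromosome 6, and the 95% bootstrap interval over members runs from 34.3% to 94.0%, across that bound. For the 11 members on chromosome 6 alone 62.3% was left (34.3% to 72.9%), and 34.2% when the median of the other genes in their 60-gene windows (0.19 and 0.29) was subtracted instead. A change of the histones beyond their chromosomes or their region therefore cannot be told apart from the shift, because the interval crosses the bound and the window value lies between the bounds.

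The lower cell cycle genes and the higher interferon genes were weighed against technical sources. Of the 70 cell cycle genes 69 were lower with GC content and length trends removed, which argues against these trends. At equal depth 68 were lower, but thinning keeps each gene's expected share of its library, so a bias linked to depth is not excluded. Of the 35 interferon genes 20 rose in the fit that left the fewest (without MCF7EV replicate 1) and 27 with the trends removed, which argues against a single library and these trends. At equal depth 26 rose, which for the same reason does not exclude depth. A slower culture, a denser dish or drift between the lines could give either pattern as well as the construct could, and with 1 line of each kind none of these was tested.

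Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split called 3607 genes (edgeR), and the highest of the 9 others called 0. At an unadjusted p under 0.05 the others had 67 to 1151 genes and the real one 5731. Each of the 9 others holds libraries of both lines on each side. The line difference thus adds to the spread within the sides and lowers these counts. The count of 0 therefore does not show how many genes are called without a difference between the lines. For gene lists tested by camera the real split called 9 and the highest other 8, but the other splits keep part of the line difference.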
